A study of Mus musculus with 16 samples.

How the data were processed

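The series measured RNA bound to tagged ribosomes of prepronociceptin neurons in the mouse hypothalamus. Per the labels, PNOC-L10a-EGFP mice on a C57BL/6N background, 10 to 12 weeks old, received chow or a high-fat diet for 3 days. In such mice the ribosomal protein L10a, fused to a green fluorescent protein, marks ribosomes of the targeted cells, and an antibody against the fluorescent protein precipitates these ribosomes with their RNA (BacTRAP). For each diet the labels list 4 input libraries, from RNA of the hypothalamus before precipitation, and 4 immunoprecipitate libraries, 16 in all. They do not say whether a library came from 1 animal or from a pool, so the p-values measure only the spread between these samples. They also do not say whether an input and an immunoprecipitate with the same number came from the same tissue.

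Per the labels' protocols, the hypothalamus was dissected and frozen, RNA was purified with a column kit for small amounts, and cDNA was made and amplified with the Ovation RNASeq V2 system, using oligo(dT) and random primers, before Nextera XT library preparation. Amplification of small RNA amounts, and unequal loss of short transcripts, can shift levels between input and immunoprecipitate. The labels do not say whether reads were assigned by strand, so a gene and an antisense partner may share reads. Per the submitters' processing notes, HISAT2 2.1.0, StringTie 1.3.4d, Cufflinks 2.2.1 and Cuffdiff were used with the mouse build GRCm38.p6. The version and settings of Cuffdiff and the way libraries were scaled are not given in the sources used here.

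The authors deposited 1 table for each diet, in the column layout of Cuffdiff per the file headers. Each table gives 1 FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for the input group and 1 for the immunoprecipitate group, both made by the authors. The deposited log2 fold is the immunoprecipitate FPKM over the input FPKM. Recomputed from the deposited FPKM, it differed by at most 1.31e-05. The authors' test statistic, a signed score without a unit, and the authors' p-value and q-value stand beside it in the deposited tables. Every entry of both tables is marked significant, with q-values from 0.000379 to 0.0499. A gene that is not listed here may have been untested, not significant or left out, and cannot be called unchanged.

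The chow table held 7234 entries for 7232 gene identifiers, and that of the high-fat diet held 7072 entries for 7069 identifiers. Entries that repeat the values of a locus for several identifiers were merged into 1 test, which left 6686 tests for chow and 6540 for the high-fat diet. Of the identifiers, 7226 and 7063 were found in the GENCODE M21 annotation of GRCm38. Among tests with a single identifier, 99.8% in each table overlapped the locus of that gene in the annotation. The deposited span is often wider than the annotated gene, as for Pmch. The fold was infinite, with 1 group listed at 0, in 15 chow tests and 16 high-fat tests, which entered counts but no averages of folds. All 271 p-values that occur in both tables had the same q-value. With Benjamini-Hochberg adjustment, these pairs imply a median of 48459 tests adjusted together (48363 to 48815), or 24230 per table. It is not stated whether the FPKM of both tables were scaled together.

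Because the tables hold no value per library, no read depth or replicate values were known, no model was refitted, and no library could be left out. The call for each diet was therefore the authors' q-value at a threshold of 0.05, as planned for this case. Both tables rest on different libraries, so no control was shared between the diets. No column of per-sample values was set aside (0 such columns).

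The difference between diets was computed for each test listed in both tables with a finite fold and at least 1 FPKM in input or immunoprecipitate of each diet. It was the high-fat log2 fold minus the chow log2 fold, centred on its median of 0.0062. The standard error of each fold was recovered as the log2 fold divided by the deposited statistic. A two-sided z-test with Benjamini-Hochberg adjustment was computed with SciPy 1.17.1. The test is a normal approximation, which no exact test can replace without values per library, and it is conservative, because the normal deviate of the deposited p-value was 1.96 times the statistic in chow and 1.95 times in the high-fat table (medians over 3365 and 3448 tests). Differences were simulated on 200 of the 5149 tests, with noise of the size of these standard errors. The z-test recovered 6.5% of simulated differences of 1 log2 unit, 80.0% of differences of 2 and 90.5% of differences of 3. False calls numbered 0, 3 and 9. The deposited folds differed less between diets than this noise, so these rates do not describe the test as applied to them. A difference had to reach 0.85 log2 units for an unadjusted p of 0.05 at the median standard error.

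Before the data were examined, the tests, the alternatives and 29 gene lists with 407 entries were fixed, the lists covering neuron classes, neuropeptides, receptors, transcription factors, markers of other cell types and of neighbouring tissue, organelle and nuclear transcripts, and metabolic and stress pathways. For each list the enriched, depleted and unlisted members were counted and the median log2 fold of listed members was set against 10000 random lists of the same size, drawn from the listed tests and matched on FPKM in 10 bins. The percentile describes these tables and is not a p-value. Counts adjusted over the list alone gave unlisted members a p of 1 and are lower bounds. No set test with a correlation between genes could be run without library values. As a check on the deposited chow folds, 40 random lists over 6671 tests had a median percentile of 62.3 (0.22 to 97.0), somewhat above the middle of the scale. A random list whose folds were raised by 3 log2 units reached a percentile of 100.

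Genes were named by a rule fixed at the same time. It took Pnoc and Rpl10a, and for each diet the 10 highest and 10 lowest log2 folds among called protein-coding genes with a proper symbol and at least 5 FPKM in the higher group. It also took up to 4 called members of each list with the largest absolute fold, and the 5 smallest p for the diet difference if none passed. The genes Gad1, Gad2, Map2, Sst, Cartpt, Ghrh, Gal, Pdyn, Npvf and Ucn3 were added after their values were seen. So were Oprl1, Slc17a6, Tbr1, Itm2a, Slco1a4, Pdgfrb, Kcnj8, Aldoc, Calb2 and Haus1, and genes described as not listed. Some genes that the rule takes are not reported here. Transcript length was the longest annotated transcript of a gene. Gene Ontology terms deposited beside the genes were tested, as an addition after the data were seen, with a two-sided Fisher's exact test of enriched against depleted among listed tests, for terms with at least 20 listed tests. On simulated data the planted term ranked 1 and 0 of 200 random terms were called.

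Alternatives fixed in advance were a q-value of 0.01, at least 1 FPKM, at least a 2-fold difference, folds recomputed with a pseudocount of 1 or 0.1, centring on the median of listed tests, and protein-coding genes only. For the diet difference they were no centring, at least 5 FPKM, an adjusted p of 0.01 and standard errors 1.5 times as large. With the filter at 1 FPKM the authors' q-value was kept, since it cannot be adjusted again without the unlisted p-values. Standard errors rescaled to the deposited p-values, with and without the FPKM filter, were added after the data were seen. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots used Matplotlib 3.10.9.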

Results

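Ribosome-bound RNA of hypothalamic neurons that express prepronociceptin (Pnoc, the precursor of the opioid-like peptide nociceptin) was compared with RNA of the whole hypothalamus in mice fed chow or a high-fat diet for 3 days. Each diet had 4 input and 4 immunoprecipitate libraries. The processed data were the authors' deposited tables of significant differences between immunoprecipitate and input, 1 for each diet, with a single FPKM per group and no value per library. Read depth and replicate values are therefore unknown, and all FPKM, log2 folds and q-values given for a single diet are the authors' deposited values. Both tables together allow 3 comparisons, which are enrichment on tagged ribosomes in chow-fed mice, the same enrichment after 3 days of high-fat diet, and the difference between them.

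The chow comparison asks which transcripts were carried by tagged ribosomes. Pnoc itself rose from 4.62 FPKM in the input to 19.9 FPKM in the immunoprecipitate, a 4.31-fold enrichment (log2 fold 2.11, q = 0.000379, authors' deposited table). It is identified as ENSMUSG00000045731 and lies on the minus strand of chromosome 14 at 65400673 to 65425472 (GRCm38.p6). Transcripts of other peptide neurons were enriched to a similar degree, among them Gnrh1 (gonadotropin-releasing hormone, log2 fold 2.81) and Pmch (melanin-concentrating hormone, log2 fold 2.23). Markers of astrocytes, oligodendrocytes and microglia were depleted to list medians between 9.40% and 12.7% of their input level. Rpl10a, the gene of the ribosomal protein that carries the tag, had a log2 fold of 0.32 (q = 0.0366), which became -0.10 once folds were centred on the median of the listed tests.

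In the authors' deposited chow table, 3597 tests were enriched and 3089 depleted at a q of 0.05. Enrichment was shallow, with a median of 1.52-fold among enriched tests, while the median depleted transcript stood at 41.0% of its input level. At least a 2-fold difference was reached by 293 enriched and 1920 depleted tests, which turned the share of enriched tests from 53.8% to 13.2%. The median log2 fold of listed tests with at least 1 FPKM was 0.41, and 3118 tests lay above that value. Because the centre is a median of listed tests, that count was largely set by construction. It does not test whether enrichment withstands a shift in scale. The table holds significant tests only, with the smallest enriched log2 fold at 0.29.

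The 10 named genes with the highest deposited enrichment in chow were Gnrh1, Mup6, Hist1h4f, Pmch, Pnoc, Crabp1, Cd59b, Prph, Tac2 and Cbln2, with log2 folds from 2.81 down to 1.85. Pmch was the most abundant of them and went from 460 to 2151 FPKM, while Gnrh1 went from 1.33 to 9.33 FPKM. Crabp1, a retinoic acid binding protein, rose from 9.23 to 38.3 FPKM, and Prph, the intermediate filament peripherin, from 2.90 to 11.3 FPKM. Tac2, the precursor of neurokinin B, rose from 37.4 to 141 FPKM, and Cbln2, a secreted organiser of synapses, from 7.78 to 28.2 FPKM. Mup6 (log2 fold 2.52) and Hist1h4f (2.49) belong to families of near-identical copies, so the reads behind their values are uncertain. Cd59b (1.97) has a related gene and may share some reads with it.

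Genes of GABAergic neurons were enriched as a group in the deposited chow table. Of 11 fixed members, 9 were enriched, 1 was depleted and 1 was not listed, with a median log2 fold of 1.10 that lay at percentile 100 of random lists. The homeobox genes Dlx6 (log2 fold 1.27) and Dlx2 (1.19) and the zinc finger gene Sp9 (1.17) were among its leading members, and the GABA-synthesising enzymes Gad1 and Gad2 had log2 folds of 0.82 and 0.54. Glutamatergic genes went both ways, with 3 enriched and 4 depleted of 10. Slc17a7 (0.80) and Slc17a6 (0.47), which encode vesicular glutamate transporters, were enriched. Nr5a1, a marker of the ventromedial hypothalamus, was depleted at -2.06, as were the cortical factors Neurod2 (-2.02) and Neurod6 (-1.25). Tbr1, another cortical factor of the list, was enriched (0.71).

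Pan-neuronal genes were enriched by less than the GABAergic ones, with 10 of 12 enriched in the deposited chow table and a median log2 fold of 0.62. That median lay at percentile 52.4 of random lists, so it was like that of other listed tests at similar FPKM. The difference between both lists was not tested. Snap25, a synaptic vesicle fusion protein, had the highest deposited fold among them (0.89), followed by Rbfox3 (0.74), Syn1 (0.69) and Stmn2 (0.65), and Map2 was depleted (-0.55). Subunits of GABA-A and glycine receptors had 7 enriched and 0 depleted of 18 (percentile 84.9), led by Gabrd (1.35) and Glra2 (0.84). Hypothalamic transcription factors had 10 enriched and 1 depleted of 20, with a median of 0.77 at percentile 99.95. Lef1, an effector of Wnt signalling, had the highest deposited fold of that list (1.75), and Bsx (1.37) and Zic1 (1.18) were also enriched. Markers of thalamic neurons, fixed as markers of tissue next to the hypothalamus, had 5 enriched and 0 depleted of 6. Their median log2 fold was 1.46 at percentile 100, with Gbx2 (1.48), Prkcd (1.46) and Tcf7l2 (1.15) among them.

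Neuropeptide precursors split into an enriched and a depleted set. In the deposited chow table, of 31 precursors (Pnoc not counted) 16 were enriched and 7 depleted, with a median log2 fold of 0.76 at percentile 100. The share of listed precursors that were enriched lay at percentile 67.7 of matched random lists, so that share was like theirs. Besides Gnrh1, Pmch and Tac2, somatostatin (Sst) went from 112 to 337 FPKM, Cartpt from 35.5 to 81.0 FPKM, enkephalin (Penk) from 34.3 to 77.3 FPKM and growth hormone-releasing hormone (Ghrh) from 20.2 to 43.1 FPKM. Oxytocin (Oxt), vasopressin (Avp) and orexin (Hcrt) fell to 10.5%, 11.9% and 11.1% of their input level, which is the range of the glial markers. Pomc, whose product is cleaved to melanocortins, stood at 15.6% of input, and Npvf, Ucn3 and Pdyn were also depleted. Agrp, Npy, Kiss1 and Crh were not listed in either table.

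**Figure D1:**
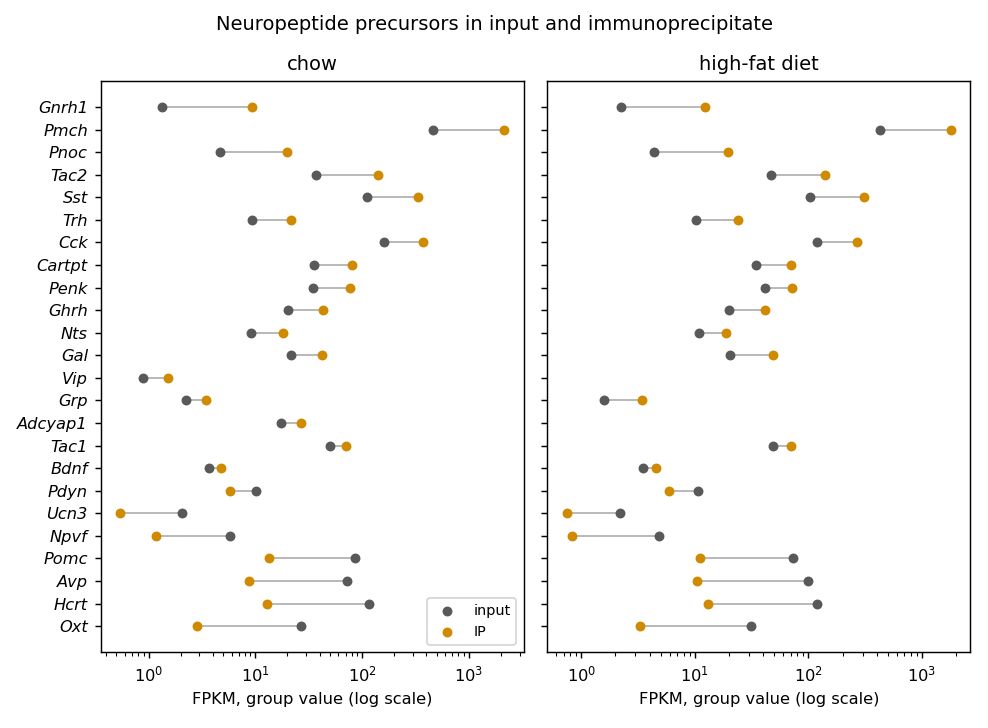
Neuropeptide precursors in input (grey) and immunoprecipitate (orange), as the authors' group FPKM on a log axis, for chow (left) and the high-fat diet (right); only precursors listed in a table have points. In both panels Gnrh1, Pmch and Pnoc lie far higher in the immunoprecipitate, and Oxt, Hcrt, Avp and Pomc far lower, with Pmch at 2151 FPKM and Oxt at 2.83 FPKM in the chow immunoprecipitate.

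Receptors of metabolic and feeding signals had 8 enriched and 4 depleted of 26 in the deposited chow table (median log2 fold 0.51, percentile 92.1). Mc4r, the melanocortin receptor, was enriched at 0.90 from a low input of 0.481 FPKM, Calcr, the calcitonin receptor, at 0.62, and Oprl1, the receptor of nociceptin, at 0.52. Adipor2, an adiponectin receptor, and Insr, the insulin receptor, were depleted at -0.91 and -0.66. Monoaminergic genes had 1 enriched and 4 depleted of 9. Hdc, which makes histamine, was enriched at 1.80, whereas the dopamine transporter Slc6a3 fell by 3.48 and Th and Ddc by 0.71 and 0.51 on the log2 scale. Of 3 cholinergic genes only Slc5a7 was listed (-0.64), and of 18 immediate early genes 2 were enriched and 3 depleted, with Dusp1 at 0.59 and Btg2 at -1.25.

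Most listed markers of cells other than neurons were depleted. All 12 astrocyte and all 12 oligodendrocyte markers were depleted in the deposited chow table, with median log2 folds of -2.98 and -3.41, or 12.7% and 9.40% of input. The water channel Aqp4 stood at 7.70% of input and the tight junction gene Cldn11 of myelin at 8.44%, while Aldoc, at 59.2%, was the least depleted astrocyte marker. Of 12 microglial markers 9 were depleted and 3 not listed (median -3.40), with P2ry12 at 6.63% of input and Csf1r at 9.04%. Oligodendrocyte precursors had 5 of 6 depleted (median -3.23) and tanycytes and ependymal cells 7 of 10 (median -2.64). Endothelial and mural markers were depleted by less, with 9 of 14 depleted, a median of -1.48 and Itm2a enriched at 0.73. That median lay at percentile 42.5 of random lists, so it was like that of other listed tests at similar FPKM. The 5 other lists of this paragraph lay at percentiles from 0 to 0.91.

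Markers of pituitary, choroid plexus and blood were measurable in the input and mostly depleted on ribosomes. In the deposited chow table, of 6 pituitary genes 4 were depleted (median -3.19), with growth hormone (Gh) at 781 FPKM in the input and 96.4 FPKM in the immunoprecipitate. Prl fell to 9.69% of input, while Cga, the common subunit of glycoprotein hormones, stood at 73.9%. Choroid plexus genes had 4 of 6 depleted (median -1.04), with Ttr, which carries thyroxine, at 7.83% of input. Their median lay at percentile 30.1 of random lists, against 0.02 for pituitary and 0.8 for blood cell genes. All 5 blood cell genes were depleted (median -2.71), although the globin genes share reads between near-identical copies. Among 8 striatal genes Ppp1r1b was depleted (-2.15) and Penk enriched (1.17).

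The deepest depletion was that of RNA outside the cytosol. In the deposited chow table, of 13 mitochondrially encoded transcripts 8 were listed, all depleted, with a median log2 fold of -5.73 or 1.89% of input. Among them mt-Co1 went from 9224 to 168 FPKM and mt-Nd3 from 17.9 to 0.283 FPKM. Nuclear copies of mitochondrial genes exist, and mt-Nd5 and mt-Nd6 share a deposited locus on opposite strands, so their separate values are uncertain. Of 10 nuclear non-coding RNAs 4 were listed, all depleted (median -4.16), including Malat1 at 2.52% and Neat1 at 3.76% of input. Among protein-coding genes with at least 5 FPKM in the higher group, the lowest after the mitochondrial transcripts were Cd9 (-4.44), the myelin gene Ermn (-3.99), Ly86 (-3.95) and P2ry12 (-3.91).

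Housekeeping and pathway lists differed in direction and size in chow. Of 76 cytosolic ribosomal protein genes 5 were enriched and 10 depleted in the authors' deposited table (median -0.33), with Rps12 at -0.66 and Rps27a at 0.56. Adjusted over the list alone, at least 10 of these 15 passed, and in all other lists of both diets the number of called members was the same as over all tests. Genes of the unfolded protein response had 7 enriched and 0 depleted of 16 (median 0.55, percentile 72.6), led by Chac1 (0.95) and Calr (0.61). Lipid and cholesterol genes had 2 enriched and 4 depleted of 18 (median -1.54), with the desaturase Scd1 at -2.81 and the carnitine palmitoyltransferase Cpt1a at -2.71. Glucose-sensing genes had 3 enriched and 2 depleted of 8, with Ucp2 at -1.29 and the potassium channel subunit Kcnj11 at 0.51. Their median of 0.40 (percentile 33.9) became -0.011 after centring. Of 11 inflammation genes 2 were listed (median -2.26), with Tlr4, the endotoxin receptor, at -3.98 and Nfkbia at -0.54.

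**Figure D2:**
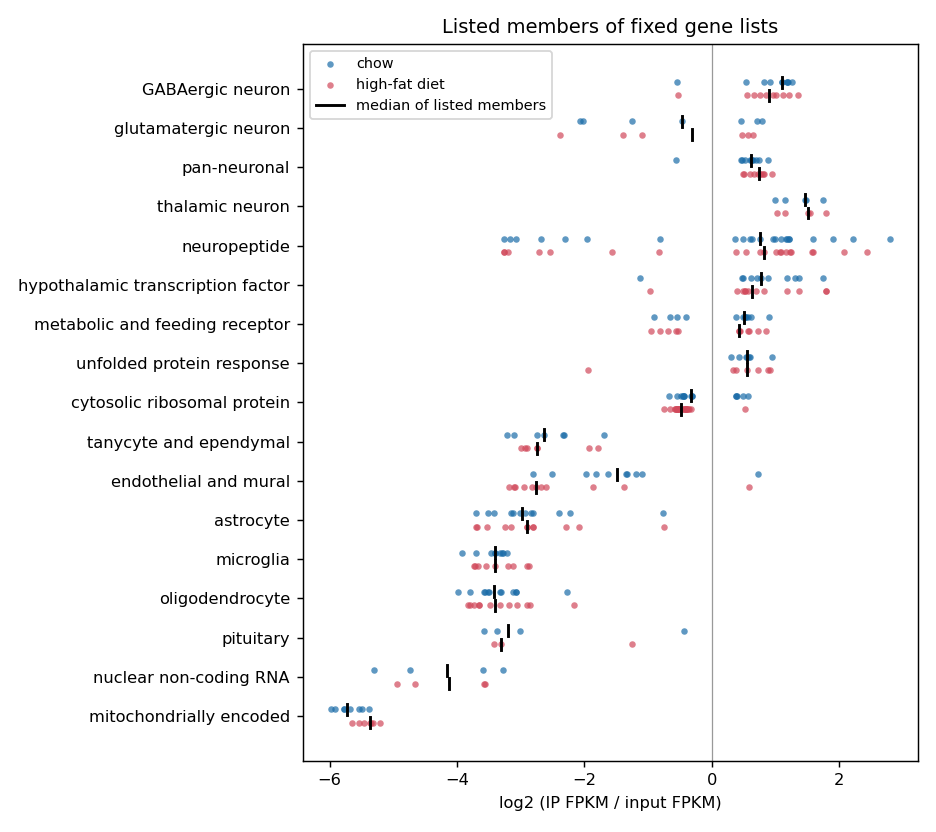
Authors' log2 folds of immunoprecipitate over input for listed members of fixed gene lists, in chow (blue) and the high-fat diet (red); each point is a gene and black bars are medians of listed members. The space around 0 is empty because the tables hold significant tests only. Among the lists drawn, thalamic (median 1.46 in chow) and GABAergic (1.10) lists lie highest, and mitochondrially encoded transcripts (-5.73) lowest. Not every fixed list is drawn, and Pnoc, Rpl10a and the glucose-sensing genes, whose median changes sign on centring, are among those left out.

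The high-fat comparison asks for the same enrichment after 3 days of the diet. Pnoc rose from 4.35 FPKM in the input to 19.8 FPKM in the immunoprecipitate, a 4.54-fold enrichment (log2 fold 2.18, q = 0.000379, authors' deposited table), while Rpl10a was not listed. Among the highest named genes were Mup6 (2.54, uncertain as in chow), Gnrh1 (2.44), Pnoc, Pmch (2.08), Cbln2 (1.83), Lef1 (1.79), Prph (1.67), Hdc (1.66) and Crabp1 (1.63). The lowest were mt-Co1 (-5.65) and the mitochondrial transcripts mt-Nd5, mt-Cytb, mt-Co2 and mt-Nd6, followed by Gapdh (-3.96), Mertk (-3.83), Ermn (-3.82), Cldn11 (-3.80) and Gng11 (-3.78). Gapdh has many near copies and a deposited span wider than the gene, so its value is uncertain.

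In the authors' deposited high-fat table, 3613 tests were enriched and 2927 depleted, of which 212 and 1844 differed at least 2-fold. That limit turned the share of enriched tests from 55.2% to 10.3%. The median enriched test stood at 1.51-fold and the median depleted one at 39.4% of input. The median log2 fold of listed tests with at least 1 FPKM was 0.42, and 3042 tests lay above it, a count again largely set by the choice of centre.

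GABAergic and pan-neuronal genes were again mostly enriched after the high-fat diet. In the deposited high-fat table GABAergic genes had 9 enriched and 1 depleted of 11 (median 0.91), led by Dlx6 (1.36), Sp9 (1.21) and the vesicular GABA transporter Slc32a1 (1.12). Pan-neuronal genes had 10 enriched and 0 depleted of 12 (median 0.74), with Snap25 at 0.94, Nefm at 0.82 and Elavl4 at 0.80. Glutamatergic genes had 3 enriched and 3 depleted of 10, and their median of -0.31 became 0.48 when members under 1 FPKM were left out. Thalamic markers had 5 enriched and 0 depleted of 6 (median 1.52), and striatal genes 1 enriched and 5 depleted of 8, including Ppp1r1b (-2.77) and Adora2a (-2.32). Hypothalamic transcription factors had 11 enriched and 1 depleted of 20 (median 0.63), and GABA-A and glycine receptor subunits 8 enriched and 0 depleted of 18 (median 0.65).

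Neuropeptide precursors had 14 enriched and 7 depleted of 31 in the deposited high-fat table (median 0.81). The 7 depleted precursors were those depleted in chow, with Oxt and Avp each at 10.4% of input, Hcrt at 10.9% and Pomc at 15.2%. Metabolic and feeding receptors had 7 enriched and 5 depleted of 26 (median 0.43), with the incretin receptor Glp1r at 0.85, Calcr at 0.72 and the leptin receptor Lepr at -0.95. Monoaminergic genes had 1 enriched and 1 depleted of 9, Hdc at 1.66 and Slc6a3 at -3.49, and Slc5a7 was again the only cholinergic gene listed (-1.10). Immediate early genes had 3 enriched and 4 depleted of 18, with Dusp1 at 0.69, Arc at -0.73 and Btg2 at -0.78.

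Most listed non-neuronal markers were again depleted after the high-fat diet. In the deposited high-fat table all 12 astrocyte markers (median -2.91), all 12 oligodendrocyte markers (-3.40), 9 of 12 microglial markers (-3.41) and 5 of 6 precursor markers (-3.02) were depleted. Tanycytes and ependymal cells had 7 of 10 depleted (-2.74), choroid plexus 3 of 6 (-1.69), pituitary 3 of 6 (-3.31) and blood cells 3 of 5 (-2.91). Endothelial and mural markers had 10 of 14 depleted and a median of -2.76, with Ly6c1 at -3.19 and Flt1 at -3.10. Their median lay at percentile 0.275 of random lists, against 14.6 for choroid plexus genes. Mitochondrially encoded transcripts (7 of 13, median -5.37) and nuclear non-coding RNAs (4 of 10, median -4.12) were again lowest.

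Of 76 cytosolic ribosomal protein genes 1 was enriched and 24 depleted in the deposited high-fat table (median -0.49), with Rps12 at -0.76 and Rpl37 at -0.66. Unfolded protein response genes had 6 enriched and 1 depleted of 16, with Creld2 at 0.91 and Atf3 at -1.94. Lipid and cholesterol genes had 3 enriched and 4 depleted of 18, and inflammation genes 0 enriched and 2 depleted of 11, namely Cxcl10 (-2.90) and Socs3 (-1.85). Glucose-sensing genes had 4 enriched and 2 depleted of 8, led by the potassium channel regulator Abcc8 (1.07), and their median of 0.42 became -0.0052 after centring.

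The difference between diets asks whether 3 days of high-fat diet changed which transcripts tagged ribosomes carried. No gene passed the test of that difference, and the enrichment of Pnoc differed by 0.07 log2 units between the diets. The gene with the smallest p was Rdh13, a retinol dehydrogenase, whose immunoprecipitate stood at 6.26 FPKM in chow and 6.04 FPKM after the high-fat diet while its input stood at 9.45 and 17.8 FPKM. Its log2 fold was lower after the high-fat diet by a centred difference of -0.97 (SE 0.42 from the statistics of the authors, p = 0.0215, adjusted p = 1). The p is a normal approximation, since no exact test can be run without values per library. The next 4 were Slc10a4 (0.73, SE 0.50), Sptssa (0.67, SE 0.46), Cga (-0.82, SE 0.57) and Arhgef10 (0.61, SE 0.47), all with an adjusted p of 1.

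By the z-test computed with SciPy, 0 of 5149 tests were higher and 0 lower after the high-fat diet, and 1 had an unadjusted p under 0.05 where chance alone would give 257. That deficit and a standard deviation of z of 0.31 show that the recovered standard errors, with a median of 0.43, were wide. With standard errors rescaled to the p-values of the authors, an alternative chosen after the data were seen, Rdh13 was lower (adjusted p = 0.0364) and no test was higher. In that z-test 22 tests had an unadjusted p under 0.05, with a standard deviation of z of 0.61. The deficit thus shrank but remained, so the scale of the authors' statistic does not account for all of it. Without the FPKM filter, the same standard errors from the p-values of the authors gave Rdh13 as lower (adjusted p = 0.0198) and Haus1, at 0.0983 FPKM in the high-fat input, as higher (adjusted p = 0.000529). The difference was at most 0.5 log2 units in 4982 tests (96.8%), and simulated differences of 1 log2 unit were recovered in 6.5% of cases.

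The overlap of both deposited tables was large. Of the enriched tests 3004 were listed as enriched in both diets, and 2548 were depleted in both. Independent lists drawn from the 24230 tests implied per table would share 536 and 373. Both tables compare the same kind of immunoprecipitate with the same tissue, so an overlap above that reference was bound to occur. A total of 5553 tests were listed in both tables, 1133 in the chow table only and 987 in the high-fat table only, and the difference was not tested for these. Haus1 was the 1 test with opposite directions. Across 5549 tests with finite folds in both tables, Pearson's r of the log2 folds was 0.98 and Spearman's rho 0.96, across genes that are not independent replicates and were all selected as significant, which widens the range of folds.

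**Figure D3:**
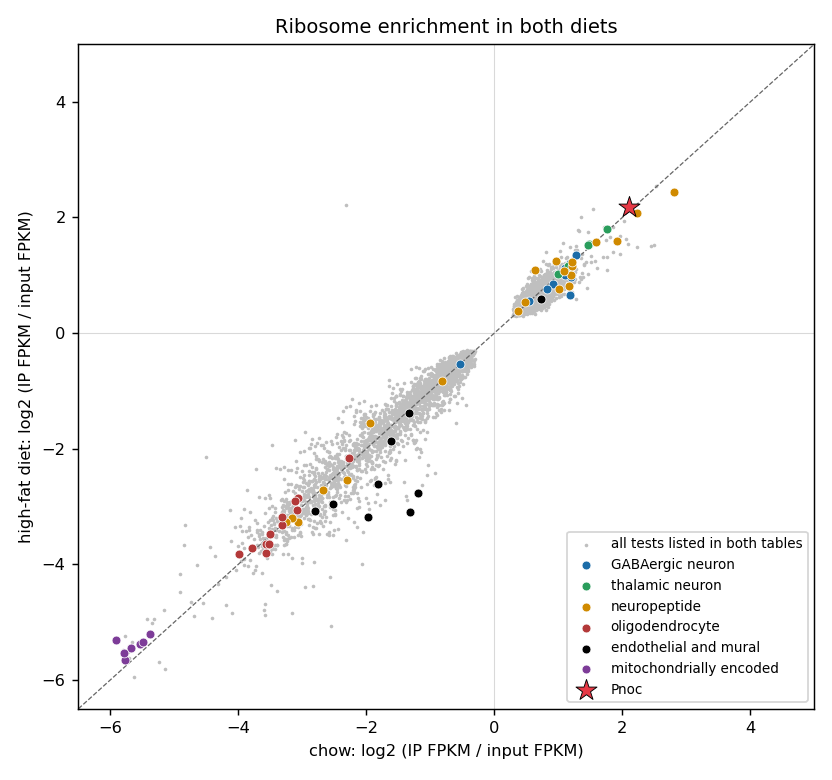
Authors' log2 fold of immunoprecipitate over input in chow (horizontal) against the high-fat diet (vertical) for tests listed in both tables with finite folds; colours mark fixed gene lists, the star marks Pnoc and the dashed line marks equal folds. Pnoc lies at 2.11 and 2.18, mitochondrially encoded transcripts lie below -5 on both axes, endothelial and mural genes lie below the line, and no test lies near 0 because only significant tests are listed.

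Gene groups that mark other cell types moved between the diets as follows, with none of these medians tested with replicates and no member of at least 1 FPKM in each diet passing the planned test. The 9 endothelial and mural genes listed in both tables all had a lower fold after the high-fat diet (median centred difference -0.44). Flt1, Slco1a4, Pdgfrb and Kcnj8 among them lay under 1 FPKM and did not enter the planned test, and Flt1 had the largest difference (-1.78). The fold was lower in 7 of 12 astrocyte genes (median -0.0029), 3 of 3 pituitary genes (-0.29) and 3 of 3 blood cell genes (-0.23). It was higher in 8 of 12 oligodendrocyte genes (0.04), 6 of 9 microglial genes (0.18) and 4 of 5 oligodendrocyte precursor genes (0.24). Pan-neuronal genes were higher in 9 of 10 by a small median of 0.05, while neuropeptide (15 of 21 lower, -0.04) and GABAergic genes (5 of 10 lower, -0.03) had medians near 0. Input levels of neighbouring tissue also differed between the deposited tables, which may not share a scale and give no test of this, although the median input of all shared tests differed by only -0.01 log2 units. Gh stood at 781 FPKM in the chow input and 204 FPKM in the high-fat input, Ttr at 54.7 and 8.89, and Cga at 72.6 and 22.1, whereas Prl stood at 146 and 243 and Ppp1r1b at 21.0 and 33.9. The 5 listed thalamic markers were all lower in the high-fat input (median log2 difference -0.26) and in the high-fat immunoprecipitate (-0.22).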

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

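Both tests named here used standard errors rescaled after the result was seen, and in the planned test of the difference between diets Rdh13 did not pass and Haus1 was left out by the FPKM minimum. Haus1, a subunit of the augmin complex of the spindle, differed between the diets, with a centred difference of 4.54 log2 units (high-fat minus chow) from deposited log2 folds of -2.32 in chow and 2.22 after the high-fat diet. Its authors' FPKM were 1.00 in the input and 0.20 in the immunoprecipitate for chow, and 0.0983 and 0.458 for the high-fat diet, and before rounding none reached the minimum of 1 FPKM. Rdh13 differed by -0.97 log2 units, from -0.59 in chow to -1.56 after the high-fat diet, and its immunoprecipitates were at 6.26 and 6.04 FPKM. No explanation was tested for either gene. Because the tables hold no value per library, no library could be compared with the others of its group, and no other split of the samples into groups could be counted.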

How the results depend on the processing

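The standard errors rescaled to the deposited p-values were chosen after the data were seen, and all other alternatives were planned. No paired analysis was possible because the deposited columns carry no libraries. For the same reason leaving out each replicate was not run, and the adjustment over genes with at least 1 FPKM could not be recomputed. Counts at a q of 0.01, at least 1 FPKM and for protein-coding genes stayed within 1.5 times the reported counts in both diets. Those after centring did too, but this is no test. Centring on the median of listed tests largely sets the enriched count by construction, and a positive centre cannot lower the depleted one. At least a 2-fold difference left 293 enriched and 1920 depleted tests in chow, 212 and 1844 after the high-fat diet, and 115 enriched in both diets. A pseudocount of 1 with at least a 1.5-fold difference left 1506 and 1897 in chow and 1435 and 1803 after the high-fat diet. A fold limit lowers counts by construction, and how much of the drop came from the pseudocount was not tested. The difference between diets gave 0 tests in both directions without centring, with at least 5 FPKM, at an adjusted p of 0.01 and with standard errors 1.5 times as large. Rescaled standard errors gave 0 higher and 1 lower, and without the FPKM filter 1 higher and 1 lower. Centring turned the median of glucose-sensing genes to -0.011 in chow and -0.0052 after the high-fat diet, Rpl10a in chow to -0.10 and Slc2a3 in chow to -0.0053, because all lay below the centre of 0.41 or 0.42. Leaving out members under 1 FPKM turned the glutamatergic median after the high-fat diet to 0.48, since fewer members entered. Without a change of sign, 18 list medians and 137 named values moved on centring, which lowers every fold, and 11 list medians and 66 named values moved with a pseudocount of 1, which draws every fold towards 0. Read depth, which the tables do not give, limits how far low genes such as Haus1 can be read.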

Other observations

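The Gene Ontology tests, the length trend and the tests of the 3 patterns described at the end were chosen after the result was seen, except the length-matched test of thalamic markers. Among listed tests with annotation, 55.6% were enriched in chow and 57.3% after the high-fat diet, and terms were compared with these shares. Fisher's exact test treated genes as independent, which they are not, and terms were not matched on FPKM. In chow, 3533 of 3597 enriched tests but 2578 of 3089 depleted tests had at least 1 FPKM. For terms with many low genes, a lean towards depletion can therefore not be told apart from their level. The same holds for a lean towards enrichment in terms with many abundant genes. In chow, random lists matched to the FPKM of pan-neuronal genes had a median log2 fold of 0.62. Lists matched to endothelial and mural genes had -1.39. Nuclear genes of mitochondria leaned towards enrichment, in contrast to the transcripts encoded by the mitochondrial genome. The term mitochondrion had 481 of 661 listed tests enriched in chow (Fisher's exact test, adjusted p = 4.12e-19) and 453 of 630 after the high-fat diet (6.51e-13). All listed genes of the large mitochondrial ribosomal subunit were enriched, 43 of 43 and 36 of 36. RNA splicing (82 of 96 and 83 of 91 enriched), synapse (149 of 194 and 150 of 190), synaptic vesicle membrane (36 of 38 and 34 of 35) and the proteasome (33 of 36 and 35 of 38) leaned the same way. Regulation of transcription (162 of 249 and 156 of 247 depleted), DNA-binding transcription factor activity (89 of 129 and 84 of 132), collagen-containing matrix (64 of 81 and 62 of 76), angiogenesis (39 of 53 and 41 of 56), myelination (19 of 23 and 19 of 23) and innate immune response (42 of 62 and 45 of 62) leaned towards depletion. The term myelin sheath leaned the other way from myelination, with 72 of 93 and 79 of 98 enriched. In all, 63 of 445 terms leaned towards enrichment and 45 towards depletion in chow, and 68 and 37 of 434 after the high-fat diet.

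Folds of short transcripts were larger in both directions, across genes selected as significant. Spearman's rho of the log2 fold with transcript length was -0.33 in chow and -0.26 after the high-fat diet among enriched tests, and 0.28 and 0.25 among depleted tests. Among 2826 tests enriched in both, rho of the diet difference (not centred) with length was 0.34, against 0.16 among 2023 depleted tests. In the enriched tests the median difference was -0.08 in the shortest of 5 groups of similar size (174 to 1549 bases) and 0.04 in the longest (4258 to 21452 bases). Cytosolic ribosomal protein genes had a median diet difference of -0.10, with 10 of 11 listed members lower. Mitochondrially encoded transcripts were the reverse, with 7 of 7 less depleted after the high-fat diet (median 0.17).

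Glial, microglial and pituitary transcripts lay at a similar low level on ribosomes, with medians of the 5 lists (astrocyte, oligodendrocyte, precursor, microglial and pituitary) within 0.50 log2 units of each other in the wider diet. Carry-over of all bulk RNA alike is argued against, since mitochondrially encoded transcripts lay lower than glial and microglial ones by a difference of -2.18 log2 units in the nearer diet. Listing of significant tests only is argued against for the astrocyte, oligodendrocyte and precursor lists, of which 96.7% of members were listed as depleted, but stays open for the microglial and pituitary lists, with 66.7% in the lower diet. Carry-over of cytoplasmic RNA of other cells at 1 share stays open too, because those 5 lists were picked after their medians were seen and the medians of all 9 lists of other cells spanned 2.38 log2 units in chow. In chow, endothelial and mural (35.8% of input), choroid plexus (48.8%), tanycyte and ependymal (16.1%) and blood cell genes (15.3%) lay higher. After the high-fat diet these lists stood at 14.7%, 31.1%, 14.9% and 13.3%. The further vascular list described below stood at 20.8% in chow and 19.1% after the high-fat diet. Cga (73.9%) and Aldoc (59.2%) also lay higher in chow, and whether tagged cells express such genes was not tested.

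Markers of thalamic neurons were enriched more than pan-neuronal genes, a pattern that may reflect tagged ribosomes in such neurons, within or beside the dissected tissue. A general enrichment of neuronal RNA stays open. The thalamic median exceeded the highest pan-neuronal fold by 0.57 log2 units in the nearer diet, against a median standard error of a thalamic fold of 0.34. That standard error was recovered from the deposited statistic and is wide, but the gap restates the pattern and cannot decide. The criterion was revised more than once after the values were seen. The ranges nearly touch, since the lowest thalamic fold in chow (Calb2, 1.00) lay just above the highest pan-neuronal one (Snap25, 0.89). Transcript length is argued against, since the thalamic median stayed 0.88 above the 200 enriched genes nearest in length. Lef1 is also on the list of hypothalamic transcription factors, the other markers are not specific to the thalamus, and no value in the tables shows which cells carried the tag.

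The enrichment ratios of vascular transcripts were lower after the high-fat diet, where the 8 depleted endothelial and mural genes listed in both tables had a median diet difference of -0.62. Over all 9 listed in both, the immunoprecipitate level was lower in 7 (median -0.35) and the input level in 5 (median -0.06), across tables that may not share a scale. Less carry-over of all non-neuronal cells alike is argued against by the 33 astrocyte, oligodendrocyte and microglial genes, whose median difference was 0.025, although pituitary (-0.29), blood cell (-0.23), choroid plexus (-0.13) and tanycyte and ependymal genes (-0.10) also had lower medians. The percentile of 0.01 among matched random lists describes the genes that prompted the pattern, from 1 of 29 lists looked at, and tests nothing further. Other lists also lay outside their random ranges, so the vascular list was not singular. Pituitary (0.05), cytosolic ribosomal protein (0.31) and blood cell genes (1.11) lay below. Mitochondrially encoded (99.7), microglial (98.55) and pan-neuronal genes (98.28) lay above. A further list of vascular genes, chosen after the pattern was seen, had 6 of 6 lower with a median of -0.20 at percentile 14.45, so less vascular RNA, noise of depleted genes and an untested effect of the diet on vessels cannot be told apart with so few genes.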
